A study of Homo sapiens with 4 samples.

How the data were processed

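Total RNA of the BJ-TE fibroblast line was extracted with trizol, labelled with biotin and hybridised by the Affymetrix standard protocol, per the labels. The table used here gives 1 intensity per probe set and array, as deposited by the authors; the software that summarised and scaled these values is not given in the sources used here. Found from the values, the intensities are linear and above 0, and each array has a mean of 500.1 to 500.2 after trimming 2% at either end. The 4 arrays were therefore counted as normalized and used as deposited. Scaling to a common mean sets each array's average equal, so a change shared by most of the signal cannot be seen, and it does not equalise the upper end of the distribution.

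Groups were taken from the sample titles: ns or p73 shRNA at 40% or 100% confluence, 1 array each. No label says that the cultures were independent, so p-values measure only the spread between these 4 arrays. Of 22277 probe sets, 62 were controls and stayed out of the tests. In the annotation of the array 19064 had 1 gene symbol, 1043 had several and 2108 were not listed; 19052 of the single-gene probe sets were matched by Entrez ID to current symbols. Probe sets with several genes or none were not named. Coordinates are not given because no genome build goes with the values.

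Values were converted to log2(intensity + 11.6), where 11.6 is the 20th percentile of all values, so ratios of dim genes are understated. A gene took its probe set with the highest mean over the arrays, and genes were kept when that mean reached the median of all probe sets, 6.94 on this log2 scale, or an intensity of about 111. This left 6759 of 11963 genes, 3737 of them with a single probe set. Signal over background limits what is seen: a gene below the filter, such as TP73 or MDM2, is not shown to be absent or unchanged.

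Each comparison used limma 3.58.1 in R 4.3.3 with an additive model of confluence and shRNA over all 4 arrays, empirical Bayes moderation with an intensity trend, two-sided tests and Benjamini-Hochberg adjustment over the 6759 genes, threshold 0.05. The model has 1 residual degree of freedom, the interaction of the factors. The trend fit gave infinite prior degrees of freedom, so the error of a gene came from the average spread at its brightness and not from its own arrays. A gene whose ratios differ between stages therefore does not receive a larger error, contrary to what was foreseen when the design was set. Without the trend the prior degrees of freedom were 15.8. Ratios per stage and per vector are reported without a test. The ratios at both stages share no array, and neither do those of both vectors.

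The comparisons, the filter, the 33 gene lists, the rule for naming genes and all alternatives but those said to be added later were chosen before the data were examined. The rule names preset genes (TP73, TP63, KCNK1, CDKN1A, CDKN1B and MDM2, and 1 that is not reported here), the 12 highest and 12 lowest genes of each comparison by the smaller of their ratios among genes with the same direction in both, the 5 highest and 5 lowest by the difference between stages, and up to 4 members of each list by average change. Other list members that are named complete a small count and were chosen after their values were seen. The median of each list with 3 or more genes above the filter was set against 10000 random lists of the same size, drawn within 20 bins of mean expression, which describes these arrays and is not a test. Counts of list members are given with the adjustment over all genes and adjusted over the list alone.

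The model was tested on simulated data for the p73 shRNA comparison with 6759 genes, of which 200 changed. With equal spread at a given brightness it recovered 44.1% of 1.5-fold, 89.4% of 2-fold and 100% of 4-fold changes, and 4.91% of its 163 calls were false. With unequal spread between genes of the same brightness it recovered 13.2%, 68.2% and 100%, and 8.4% of 131 calls were false, above the nominal 5%. The simulated noise was independent between genes, with no scaling difference between arrays and no added spread between cultures. The false rates on the real arrays may therefore be higher.

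Alternatives were quantile normalization of the arrays, a pseudocount at the 5th or 40th percentile, no brightness filter or one at the 70th percentile, the mean of a gene's probe sets, moderation without the trend, the model without the other factor, and thresholds of 1.5-fold and 3-fold. Figures were drawn with matplotlib 3.10.9.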

Results

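RNA from 4 cultures of BJ-TE cells was measured, each on 1 Affymetrix expression array of 22277 probe sets. BJ-TE is a line derived from BJ human foreskin fibroblasts. The cells carried either a short hairpin RNA (shRNA) against the transcription factor p73, or a control hairpin labelled ns. Cells of each kind were collected at 40% and at 100% confluence, which gives 4 groups of 1 array. The series is titled as a study of p73 as an inhibitor of malignant transformation, and its design text names the 2 stages of confluence. Median intensity was 106 for ns shRNA and 105 for p73 shRNA at 40% confluence, and 122 and 120 at 100%. The top end was brightest on the p73 shRNA array at 40%, where the 99th percentile of intensity was 13157 against 10196 to 11420 on the other arrays. Ribosomal RNA control probe sets had a median intensity of 638 on the ns shRNA array at 40% and of 272 to 340 on the others. The 3' to 5' intensity ratio of the GAPDH control probe sets, a measure of RNA integrity, lay between 0.93 and 1.02. That of beta-actin was 1.24 (ns) and 1.09 (p73 shRNA) at 40% confluence and higher at 100%, at 1.47 and 1.38. Spearman correlations between arrays across genes ranged from 0.947 to 0.974 and were highest between both arrays of confluent cells. No group had a replicate, so ratios at a single stage or with a single vector have no replicate check. The number of arrays limits the precision of every value.

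Among markers of cell types, 15 of the 16 measured fibroblast genes lay above the brightness filter. The corresponding numbers were 3 of 21 for epithelial cells and keratinocytes (KRT10, KRT18 and LAMB3), 2 of 12 for endothelial cells (FLT1 and ENG), 1 of 12 for blood cells (LAPTM5) and 1 of 7 for melanocytes and neural crest (MITF). For smooth muscle cells and pericytes, 5 of 10 did so (CNN1, ACTA2, CSPG4, MCAM and SMTN).

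The hairpin's own target gave no usable signal. TP73 was represented by 1 named probe set, with intensities of 1.68 (ns) and 2.09 (p73 shRNA) at 40% confluence and 1.65 and 2.04 at 100%. These lie between the 2.18th and 3.84th percentile of their arrays. The probe set was at the floor on all 4 arrays, so it gives no fold change and no check on which arrays carried the p73 hairpin. TP63 was not analysed here. All 5 probe sets of the ubiquitin ligase MDM2 lay below the brightness filter.

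The p73 hairpin was compared with the control hairpin to find the genes whose expression differs when p73 is targeted in these cells. Single genes such as ACTG2, KCNK1, CADM1 and IGFBP5 fell with p73 shRNA, and 21 of 37 genes of the interferon response rose. ACTG2, the enteric smooth muscle gamma-actin, fell most by the average of both stages: its log2 ratio was -2.46 at 40% and -2.56 at 100% confluence, with intensities of 3685 (ns) and 660 (p73 shRNA) at 40%. KCNK1, a 2-pore-domain potassium channel, was lower by -1.96 at 40%, from intensity 150 to 30.0, and fell from 421 to 96.7 at 100%. A second KCNK1 probe set below the brightness filter was lower too, by -1.55 and -0.49. The adhesion molecule CADM1 was lower by -1.88 and -2.74, and IGFBP5, a binding protein of insulin-like growth factors, by -1.94 and -1.68.

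In the additive model, which tests the effect averaged over both stages, 77 of 6759 genes rose and 107 fell with p73 shRNA (limma, Benjamini-Hochberg adjusted p below 0.05). Of these 184, 179 had the same direction at both stages, which calling genes by their average itself favours. Of the 151 genes at least 2-fold at either stage, called or not, 109 (72.2%) had the same direction at both. The average log2 change of ACTG2 was -2.51 (SE 0.16, limma adjusted p 4.55e-54), that of KCNK1 -1.98 (SE 0.30, limma adjusted p 1.94e-08) and that of CADM1 -2.31 (SE 0.29, limma adjusted p 6.82e-12). These p-values treat the spread pooled over genes as known. Without the intensity trend the limma adjusted p was 5e-07 for ACTG2 and 6.28e-06 for KCNK1 and for CADM1. At least 2-fold in the same direction at both stages were 4 genes higher and 11 lower, and none was 2-fold in opposite directions, although these ratios share no array. The 4 were MT1HL1, SOX12, OAS1 and TRIM22. Over all genes the ratios at 40% and 100% correlated with Pearson r = 0.284 and Spearman rho = 0.237, across genes, which are not independent replicates. The counts depend on the model of the spread: 105 genes were called after quantile normalization, 26 higher and 48 lower without the intensity trend, 40 with the mean of a gene's probe sets and 4 without the brightness filter. With confluence left out of the limma model 0 genes were called, and 58 had an unadjusted p below 0.05, against 922 with confluence in the model. Of the 24 genes selected by size, ACTG2, MT1HL1 and IGFBP5 were called without the brightness filter and the other 21 were not.

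Besides ACTG2, KCNK1, CADM1 and IGFBP5, the 12 lower genes named by size included the vasoconstrictor peptide EDN1 (log2 ratio -1.27 at 40% and -2.01 at 100%), TGFB2, a transforming growth factor beta ligand (-1.53 and -1.12), the Notch ligand JAG1 (average -1.51), and the secreted chaperone CLU (average -1.02). The others were the actin-bundling protein LCP1 (-1.62 and -1.33), the mechanosensitive ion channel PIEZO2 (-1.11 and -1.15), TCIM (-1.96 and -1.25) and YARS2, the mitochondrial tyrosyl-tRNA synthetase (-0.94 and -0.96). For CLU, only 2 of its 3 probe sets above the brightness filter were lower by the average of both stages. Of the 12 higher genes named by size, 5 belonged to the interferon list: OAS1, TRIM22, MX1, MX2 and IFITM1. TAP2, a subunit of the peptide transporter for MHC class I, was higher by 0.81 and 0.90 (limma adjusted p 0.0394), a call lost after quantile normalization. Also higher were the transcription factor SOX12 (1.33 and 1.39), the lysophosphatidic acid receptor LPAR3 (1.10 and 0.93), the LIM-domain protein FHL3 (1.05 and 0.87), the collagen chaperone FKBP10 (0.86 and 0.91), MT1HL1 (1.59 and 1.74) and ANXA2P3 (0.93 and 1.18). MT1HL1 belongs to the metallothionein family and ANXA2P3 is a pseudogene of annexin A2, so both probe sets can also bind transcripts of near-identical genes and their identity is uncertain. All 24 passed the test in the additive model, which choosing them by size from the same arrays favours, so it is no separate support. The calls of CLU, FHL3 and FKBP10 were lost with the mean of probe sets. FHL3 and FKBP10 have 1 probe set each, so averaging left their values unchanged. In that setting the prior degrees of freedom were 13.9 rather than infinite.

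**Figure D1:**
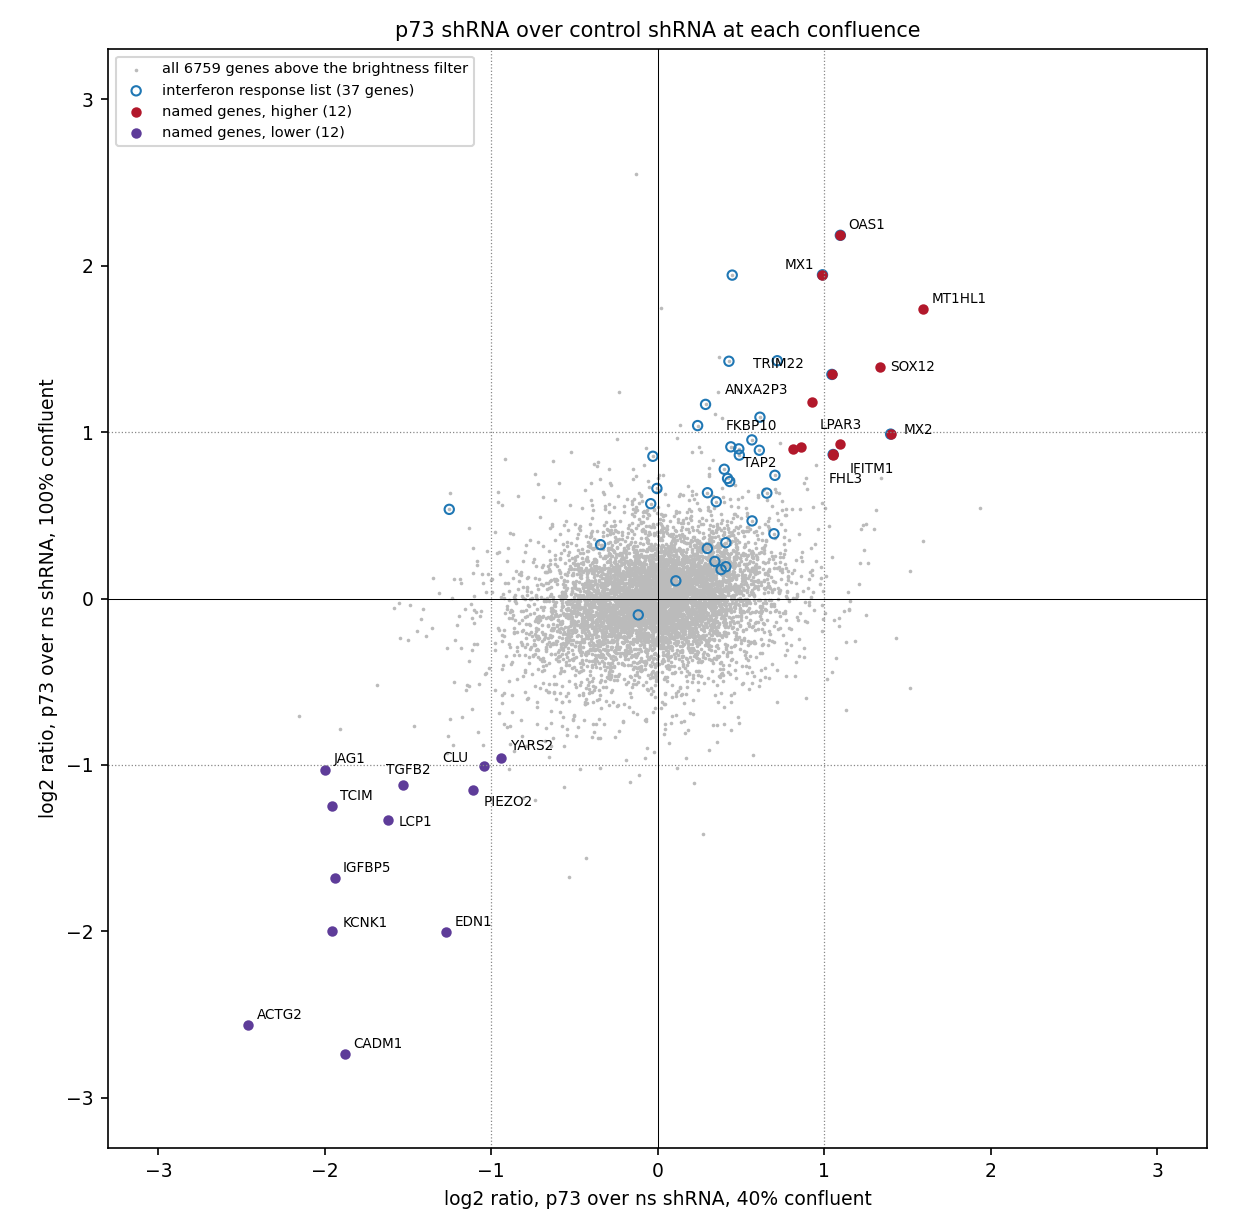
Each point is a gene: the horizontal axis is the log2 ratio of p73 over ns shRNA at 40% confluence and the vertical axis the same ratio at 100%, 1 array per group, with dotted lines at a 2-fold change. The 12 named lower genes and 12 named higher genes lie in the corners where both ratios share a sign, and the 37 interferon genes (open circles) lie mostly above 0 on both axes, with medians of 0.43 and 0.74.

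The interferon response list had the highest median of the preset lists at both stages. Of its 37 members above the brightness filter, 21 rose, none fell and 16 did not pass the test with p73 shRNA; 26 rose when adjusted over the list alone. The rise covered antiviral effectors: OAS1, a 2'-5'-oligoadenylate synthetase, was higher by 1.10 at 40% and 2.18 at 100% (average 1.64, SE 0.27, limma adjusted p 6.77e-07). MX1, a dynamin-like antiviral GTPase, was higher by 0.99 and 1.94 (average 1.47, SE 0.20, limma adjusted p 4.11e-10), TRIM22 by 1.05 and 1.35, and OAS2 by 0.45 and 1.94. Without the intensity trend the limma adjusted p was 0.000649 for OAS1 and 0.00121 for MX1. The list's median log2 ratio was 0.43 at 40% and 0.74 at 100%, both at the 100th percentile of 10000 random lists matched on mean expression, and 31 of the 37 were higher at both stages. The median difference between the stages was 0.34, which has no test. The number of interferon genes called was 17 after quantile normalization, 9 without the intensity trend, 7 with the mean of probe sets and 0 without the brightness filter. No second p73 hairpin and no cells without a hairpin were among the arrays analysed. In the list of RNA interference and double-stranded RNA sensing, 1 of 12 members rose, RIGI, a cytosolic RNA sensor (0.70 and 0.74), and the same 1 did so adjusted over the list alone; its call was lost after quantile normalization and without the intensity trend.

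Among the p53 family targets, 2 of 29 rose with p73 shRNA, 1 fell and 26 did not pass; adjusted over the list alone, 2 rose and 2 fell. PIDD1, a death-domain scaffold protein, was higher by 1.93 and 0.54, TRIM22 was the other that rose and KCNK1 was the one that fell. TRIM22 is also on the interferon list and was counted there. KCNK1 was also preset by name and is on the potassium channel list, so its fall is no separate support for a fall of p53 family targets. The list's medians were 0.02 and 0.05. CDKN1A, the cyclin-dependent kinase inhibitor p21, averaged 0.11 (SE 0.20, limma adjusted p 0.896), with intensities of 197 and 191 at 40% and 681 and 813 at 100%. CDKN1B, the inhibitor p27, averaged -0.34 (limma adjusted p 0.254).

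Genes of the cell division cycle moved little with p73 shRNA. In the G2/M and mitosis list 0 of 42 members passed, also adjusted over the list alone, with medians of -0.05 and 0.02. In the G1/S and DNA replication list 1 of 37 fell, GMNN, an inhibitor of replication licensing (-0.77 and -0.35), and adjusted over the list alone the same number fell. Of 14 cyclins, CDK inhibitors and pocket proteins, 2 fell by either adjustment: CCND1, cyclin D1 (-0.98 and -0.55), and the retinoblastoma gene RB1 (-0.87 and -0.38). The calls of GMNN, CCND1 and RB1 were lost without the intensity trend. Of 23 apoptosis regulators none passed by either adjustment, and their medians were 0.12 and 0.11, at the 94.2nd and 98.6th percentile of random lists. Of 5 replication-dependent histones none passed over all genes and 3 fell adjusted over the list alone, with medians of -0.34 and -0.18.

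Few genes of matrix, adhesion and cytoskeleton lists were called with p73 shRNA. In the collagen and fibroblast matrix list 3 of 39 fell and 1 rose, with the same counts adjusted over the list alone: the proteoglycan LUM (-1.91 and -0.78), tenascin TNC (-0.49 and -0.82) and EFEMP1 (-0.65 and -0.56) fell, and TGFBI rose (0.87 and 0.05). The TGFBI call was lost after quantile normalization, and without the intensity trend those of TNC, EFEMP1 and TGFBI were. The medians were -0.07 and -0.16, at the 4.82nd and 0th percentile of random lists. Integrins and cadherins had medians of -0.18 and -0.16 with 0 of 21 called by either adjustment, at the 1.91st and 0.02nd percentile. Among 23 genes of the SRF and actin cytoskeleton list, ACTG2 and the calponin CNN1 (-0.79 and -0.89) fell and beta-actin, ACTB, rose (0.83 and 0.23) by either adjustment; the ACTB call was lost after quantile normalization and without the intensity trend. The medians of this list were 0.00 and -0.13, at the 29.3rd and 0th percentile. Smooth muscle and pericyte markers had medians of -0.39 and -0.47, at the 2.51st and 0.04th percentile, with 1 of 5 fallen, CNN1, and 2 adjusted over the list alone. Of 15 fibroblast markers VIM and THY1 rose and LUM and PDGFRA fell, while adjusted over the list alone 4 rose and 2 fell; of these calls only that of LUM held after quantile normalization or without the intensity trend.

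Cytosolic ribosomal proteins had a median of 0.36 at 40% and 0.11 at 100%, with 0 of 26 called and 1 risen adjusted over the list alone; after quantile normalization the medians averaged -0.02. The p73 shRNA array at 40% was the one with the brightest top end. In oxidative phosphorylation 1 of 35 rose by either adjustment, ATP5MC1 (0.77 and 0.50), with medians of 0.17 and 0.05. No member passed by either adjustment among 34 genes of hypoxia and glycolysis (medians 0.03 and -0.15), 32 of amino acid and unfolded protein stress (0.06 and -0.07), 25 immediate early genes (-0.01 and -0.05), 14 of heat shock (-0.05 and 0.09) and 3 epithelial markers (-0.00 and -0.34). A single member each passed by both adjustments in 5 lists: TGFB2 fell among 21 YAP/TEAD targets (medians -0.06 and -0.09), JAG1 among 9 Notch genes (medians -0.17 and -0.15), CCND1 among 15 Wnt genes (medians -0.03 and -0.05) and the prostaglandin synthase PTGS2 among 29 NF-kB genes (medians 0.08 and 0.11), and the isopentenyl isomerase IDI1 rose among 22 cholesterol genes (medians 0.07 and 0.14). TGFB2 and the BMP antagonist GREM1 fell among 19 TGF-beta and BMP genes (medians -0.01 and -0.13), by either adjustment. IGFBP5 and PDGFRA fell among 24 PI3K and IGF genes (medians -0.07 and -0.04), with 1 more risen adjusted over the list alone. ADAMTS1 fell among 16 matrix proteases and inhibitors (medians 0.10 and 0.05), also with 1 risen adjusted over the list alone. KCNK1 fell among 5 potassium channels (medians 0.38 and 0.22), with 2 others risen adjusted over the list alone. Without the intensity trend the calls of ATP5MC1, CCND1, IDI1, GREM1 and PDGFRA were lost. Of 31 lysosome and autophagy genes (medians 0.09 and -0.02) none passed, and adjusted over the list alone 1 rose and 2 fell.

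**Figure D2:**
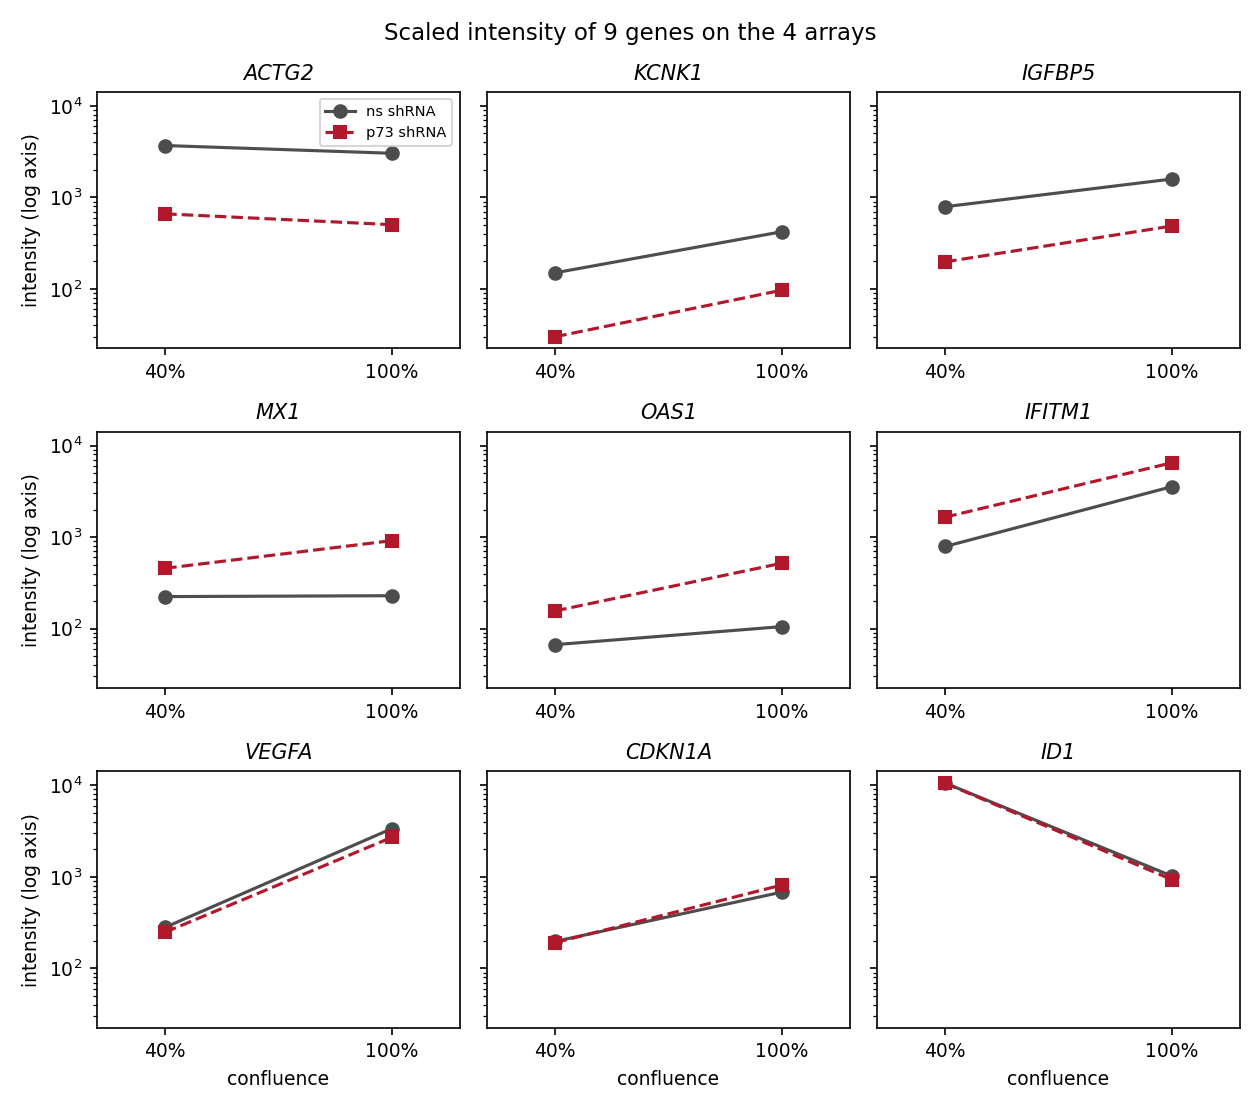
Scaled intensity of 9 genes on a log axis at 40% and 100% confluence, 1 array per point, with ns shRNA as circles and p73 shRNA as squares. ACTG2, KCNK1 and IGFBP5 lie lower with p73 shRNA at both stages and MX1, OAS1 and IFITM1 higher, while VEGFA and CDKN1A rise and ID1 falls with confluence for both hairpins.

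Confluent cells were compared with cells at 40% confluence, with the hairpins as the repeats. Of the preset lists, most genes above the brightness filter of hypoxia and glycolysis (21 of 34), fibroblast matrix (25 of 39), inflammatory factors (16 of 29) and cholesterol synthesis (14 of 22) rose at confluence, while ID1, ID2 and ID3, inhibitors of basic helix-loop-helix transcription factors, fell. VEGFA, the vascular endothelial growth factor, was higher by log2 3.53 with ns shRNA and 3.38 with p73 shRNA, from intensity 280 to 3357 with ns shRNA. ID1 was lower by -3.36 and -3.48, from 10568 to 1019. CCNG2, an atypical cyclin, was higher by 2.98 and 3.16, and CDKN1A by 1.73 and 2.03 (average 1.88, SE 0.20, limma adjusted p 1.66e-18). Without the intensity trend the limma adjusted p of CDKN1A was 8.13e-07. KCNK1 was also higher at confluence, by 1.42 and 1.38.

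In the additive model 1382 of 6759 genes rose and 1089 fell with confluence (limma, Benjamini-Hochberg adjusted p below 0.05). Of these 2471, 2449 had the same direction with both hairpins, which calling genes by their average itself favours. Of the 857 genes at least 2-fold with either hairpin, called or not, 818 (95.4%) had the same direction with both hairpins. At least 2-fold with both were 218 genes higher and 89 lower, with none in opposite directions. The ratios correlated across genes with r = 0.771 and rho = 0.711. VEGFA averaged 3.46 (SE 0.17, limma adjusted p 1.46e-89) and ID1 -3.42 (SE 0.14, limma adjusted p 6.85e-119). These p-values treat the spread pooled over genes as known, and without the intensity trend the limma adjusted p was 1.87e-09 for each. Without the brightness filter the model called 1555 genes. Any difference in handling between the stages is part of this comparison, and the 3' to 5' ratio of beta-actin was higher on both arrays of confluent cells.

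The other genes named by size were higher in both backgrounds by log2 2.59 or more: NDRG1 (3.37 and 2.94), the mTOR pathway inhibitor DDIT4 (3.33 and 2.83), the adenylate kinase AK4 (3.72 and 2.59), the secreted glycoprotein STC1 (3.18 and 2.60), ZNF395 (3.14 and 2.82), PNRC1 (2.91 and 3.01), the scavenger receptor COLEC12 (2.90 and 3.39), the complement protease homologue C1RL (2.88 and 2.93), the prostaglandin E synthase PTGES (3.02 and 2.71) and OLFML2A (2.98 and 2.60). Lower were ID3 (-3.11 and -2.85), ID2 (-2.25 and -2.10), the oxytocin receptor OXTR (-2.68 and -2.72), the haem oxygenase HMOX1 (-2.50 and -2.50), the Wnt inhibitor DKK1 (-2.50 and -2.40), the matricellular protein CCN2 (-2.35 and -2.97), DLX2 (-2.93 and -2.33), PODXL (-2.29 and -2.77), CD24 (-2.42 and -2.14), EDN1 (-2.14 and -2.87) and ENC1 (-2.03 and -2.04). All 24 passed the test, which choosing them by size from the same arrays favours.

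**Figure D3:**
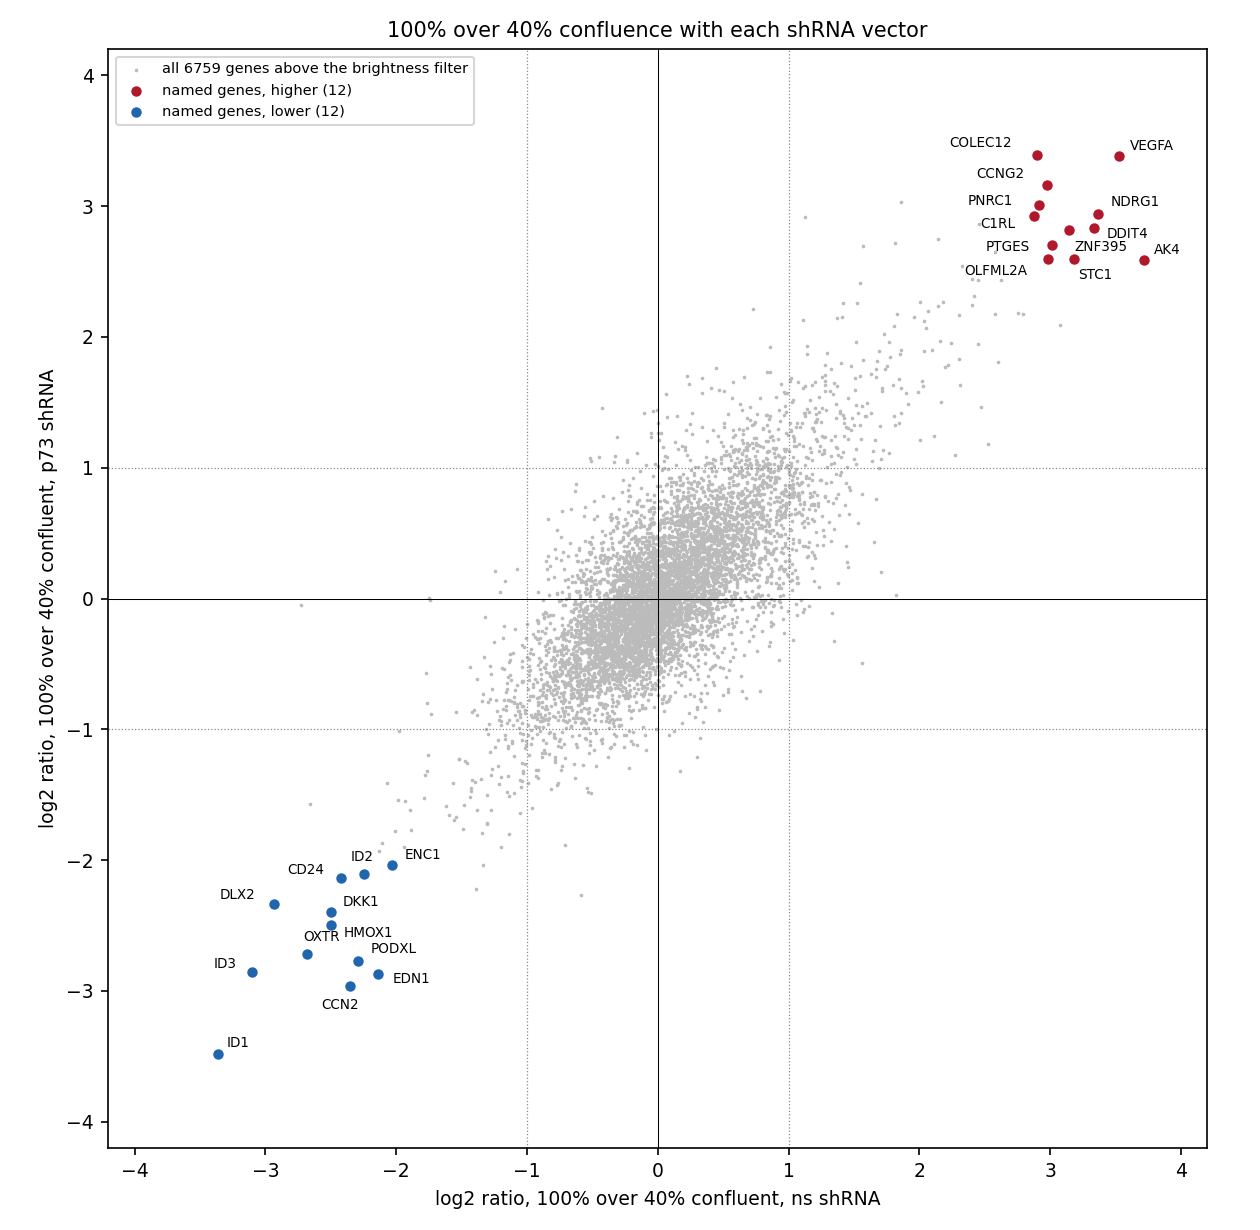
Each point is a gene: the horizontal axis is the log2 ratio of 100% over 40% confluence with ns shRNA and the vertical axis the same ratio with p73 shRNA, 1 array per group, with dotted lines at a 2-fold change. Points follow the diagonal (r = 0.771 across 6759 genes), with the 12 named higher genes at 2.59 or above and the 12 named lower genes at -2.03 or below on both axes.

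In the hypoxia and glycolysis list 21 of 34 members rose at confluence, 4 fell and 9 did not pass, and adjusted over the list alone 22 rose and 4 fell. The medians were 0.79 with ns shRNA and 0.66 with p73 shRNA, at the 100th percentile of random lists. Besides VEGFA, NDRG1, DDIT4 and STC1, the members that rose included MXI1 (2.45 and 2.86) and BHLHE40 (2.75 and 2.18). The 4 that fell were the vasodilator peptide ADM (-0.34 and -1.04) and the glycolytic enzymes GAPDH (-0.52 and -0.65), HK1 (-0.44 and -0.32) and ENO1 (-0.38 and -0.32), the last of which was not called after quantile normalization. HK1 and ENO1 were not called without the intensity trend. The 3' control probe set of GAPDH, which stayed out of the tests, changed little with ns shRNA, from 18130 at 40% to 17505 at 100%. With p73 shRNA it fell from 27310 to 19992.

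The collagen and fibroblast matrix list had 25 of 39 members risen and 1 fallen (26 and 2 adjusted over the list alone), with medians of 0.70 and 0.48. The proteoglycans DCN (2.42 and 2.31) and LUM (1.57 and 2.69), THBS2 (1.75 and 1.78) and the laminin LAMB1 (1.60 and 1.49) rose, and THBS1 (-0.78 and -0.69) fell. Of 15 fibroblast markers 10 rose and 2 fell by either adjustment, with a median of 0.86 for both hairpins; those that fell were THY1 (-0.53 and -0.75) and VIM (-0.21 and -0.45), and the sign of VIM turned after quantile normalization and its call was lost without the intensity trend. Of 16 matrix proteases and inhibitors 7 rose and 2 fell by either adjustment: ADAMTS1 (-2.13 and -1.93) and MMP3 (-1.62 and -1.59) fell, and the plasminogen activator PLAT rose (1.26 and 1.46). Their medians were 0.21 and 0.09, and without the intensity trend 4 rose and 2 fell.

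Inflammatory and interferon lists were higher at confluence. Of 29 NF-kB and inflammatory factors 16 rose and 2 fell by either adjustment (medians 0.67 and 0.64), led by the chemokines CCL7 (2.14 and 2.75) and CCL2 (1.81 and 2.72) and the cytokine IL24 (2.60 and 1.81), while CXCL12 (-1.05 and -0.88) and CXCL8 (-0.53 and -0.84) fell. Of the 37 interferon response genes 22 rose and none fell (25 risen adjusted over the list alone), with medians of 0.39 with ns shRNA and 0.76 with p73 shRNA. IFITM1, a membrane protein that restricts viral entry, was higher by 2.15 and 1.97. Of 12 RNA sensing genes IFIH1 (1.13 and 2.92), RIGI (0.59 and 0.62) and AGO3 (0.44 and 0.53) rose and TARBP2 (-0.62 and -0.87) fell by either adjustment, with medians of -0.02 and 0.30; the calls of RIGI and AGO3 were lost after quantile normalization.

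In the cholesterol synthesis and uptake list 14 of 22 rose and none fell (15 risen adjusted over the list alone), with medians of 0.59 and 0.58. The desaturase SCD (2.58 and 2.65), INSIG1 (1.83 and 2.18) and the transcription factor SREBF1 (1.84 and 1.34) led it. Lysosome and autophagy genes had 12 of 31 risen and 3 fallen (13 and 3 adjusted over the list alone; medians 0.36 and 0.10), with the iduronate sulfatase IDS at 1.03 and 0.85. PI3K and IGF genes had 13 of 24 risen and 2 fallen (14 and 2 adjusted over the list alone; medians 0.65 and 0.32). IGFBP6 (2.04 and 2.13) and the receptor PDGFRA (1.11 and 2.13) rose, and IGFBP3 (-1.52 and -1.23) and IRS1 (-0.72 and -0.38) fell.

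Of 29 p53 family targets 12 rose and 5 fell (12 and 6 adjusted over the list alone), with medians of 0.34 and 0.42. CDKN1A, GDF15 (1.14 and 1.87) and KCNK1 were among those that rose, and GADD45A (-1.79 and -1.53) led those that fell. With the stricter brightness filter the average median of this list turned to -0.19. Of the cell cycle lists, G2/M and G1/S had medians near 0. In G2/M and mitosis 8 of 42 rose and 8 fell (8 and 9 adjusted over the list alone; both medians -0.06), with CDC25C at 1.15 and 0.39 and CDC20 at -0.90 and -0.54. Without the intensity trend 2 of them rose and 4 fell. In G1/S and DNA replication 4 of 37 fell and 1 did so adjusted over the list alone (medians -0.02 and -0.05): MCM10, CDC45, CDC6 and RRM2. Of these, the call of RRM2 was lost after quantile normalization, when 3 genes of the list rose and 3 fell, and 1 fell without the intensity trend. Of 14 cyclins, CDK inhibitors and pocket proteins 5 rose and 5 fell (7 and 5 adjusted over the list alone; medians 0.25 and 0.23, at the 97.0th and 94.8th percentile): CCNG2, CDKN1A, RBL2, CDKN1B and RB1 rose, and CCND1 (-1.78 and -1.35), CCND3, CDK4, CKS2 and SKP2 fell. Without the intensity trend 4 of this list rose and 2 fell.

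In the next lists more members fell than rose at confluence, and the medians were negative with both hairpins. Of 19 TGF-beta and BMP genes 10 fell and 5 rose by either adjustment (medians -0.92 and -0.53); the ID genes and CCN2 led those that fell, and LTBP1, TGFBR3, LTBP3, SMAD3 and TGIF1 rose. YAP/TEAD targets had 9 of 21 fallen and none risen by either adjustment (medians -0.35 and -0.51), with CCN2, GADD45B (-2.07 and -1.41) and tissue factor F3 (-1.59 and -1.65). SRF and actin cytoskeleton genes had 12 of 23 fallen (13 adjusted over the list alone) and 3 risen (medians -0.26 and -0.46): SMTN (-1.43 and -1.52), CSRP1 (-0.76 and -1.13) and TAGLN (-0.79 and -1.03) were lowest, and MYH10, ACTA2 and MYLK rose. Heat shock genes had 10 of 14 fallen (11 adjusted over the list alone) and none risen (medians -0.57 and -0.35), with HSPH1 at -0.62 and -1.14; without the intensity trend 6 fell. Amino acid and unfolded protein stress genes had 13 of 32 fallen and 3 risen by either adjustment (medians -0.29 and -0.30): the cystine transporter SLC7A11 (-1.89 and -1.61) and its partner SLC3A2 (-1.38 and -1.62) fell, and DDIT4, CEBPB and PDIA4 rose.

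Ribosomal proteins had 13 of 26 fallen with confluence (14 adjusted over the list alone; medians -0.15 and -0.40); all 13 calls were lost after quantile normalization, when 2 members rose, 0 fell in limma, the sign of RPS16 turned and the average median was 0.03. The 13 calls were also lost without the intensity trend. In oxidative phosphorylation 6 of 35 fell by either adjustment (medians -0.05 and -0.09), and the average median was 0.01 after quantile normalization; without the intensity trend 2 fell. Immediate early genes had 8 of 25 risen and 7 fallen by either adjustment (medians -0.00 and -0.02), with EGR1 at 2.05 and 2.07 and the growth factor HBEGF at -1.89 and -1.77. Integrins and cadherins had 4 of 21 risen and 6 fallen by either adjustment (medians -0.14 and -0.09), from ITGA4 (0.71 and 1.37) to the focal adhesion protein ZYX (-1.42 and -1.39), and without the intensity trend 3 rose and 2 fell. Wnt genes had 5 of 15 risen and 4 fallen (medians -0.07 and 0.21), apoptosis regulators 7 of 23 risen and 5 fallen (medians -0.08 and -0.10) and potassium channels 2 of 5 risen and 2 fallen (medians 0.24 and 0.10), each by either adjustment; without the intensity trend 7 apoptosis regulators rose and 3 fell. Notch genes had 3 of 9 risen (4 adjusted over the list alone) and 1 fallen, JAG1 (medians 0.29 and 0.27), and without the intensity trend 1 rose and 1 fell. Of 5 smooth muscle markers ACTA2 rose and SMTN fell (medians 0.07 and -0.26), and of 3 epithelial markers LAMB3 rose (medians 0.09 and -0.04), each by either adjustment. No histone of 5 passed by either adjustment (medians -0.20 and -0.07).

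**Figure D4:**
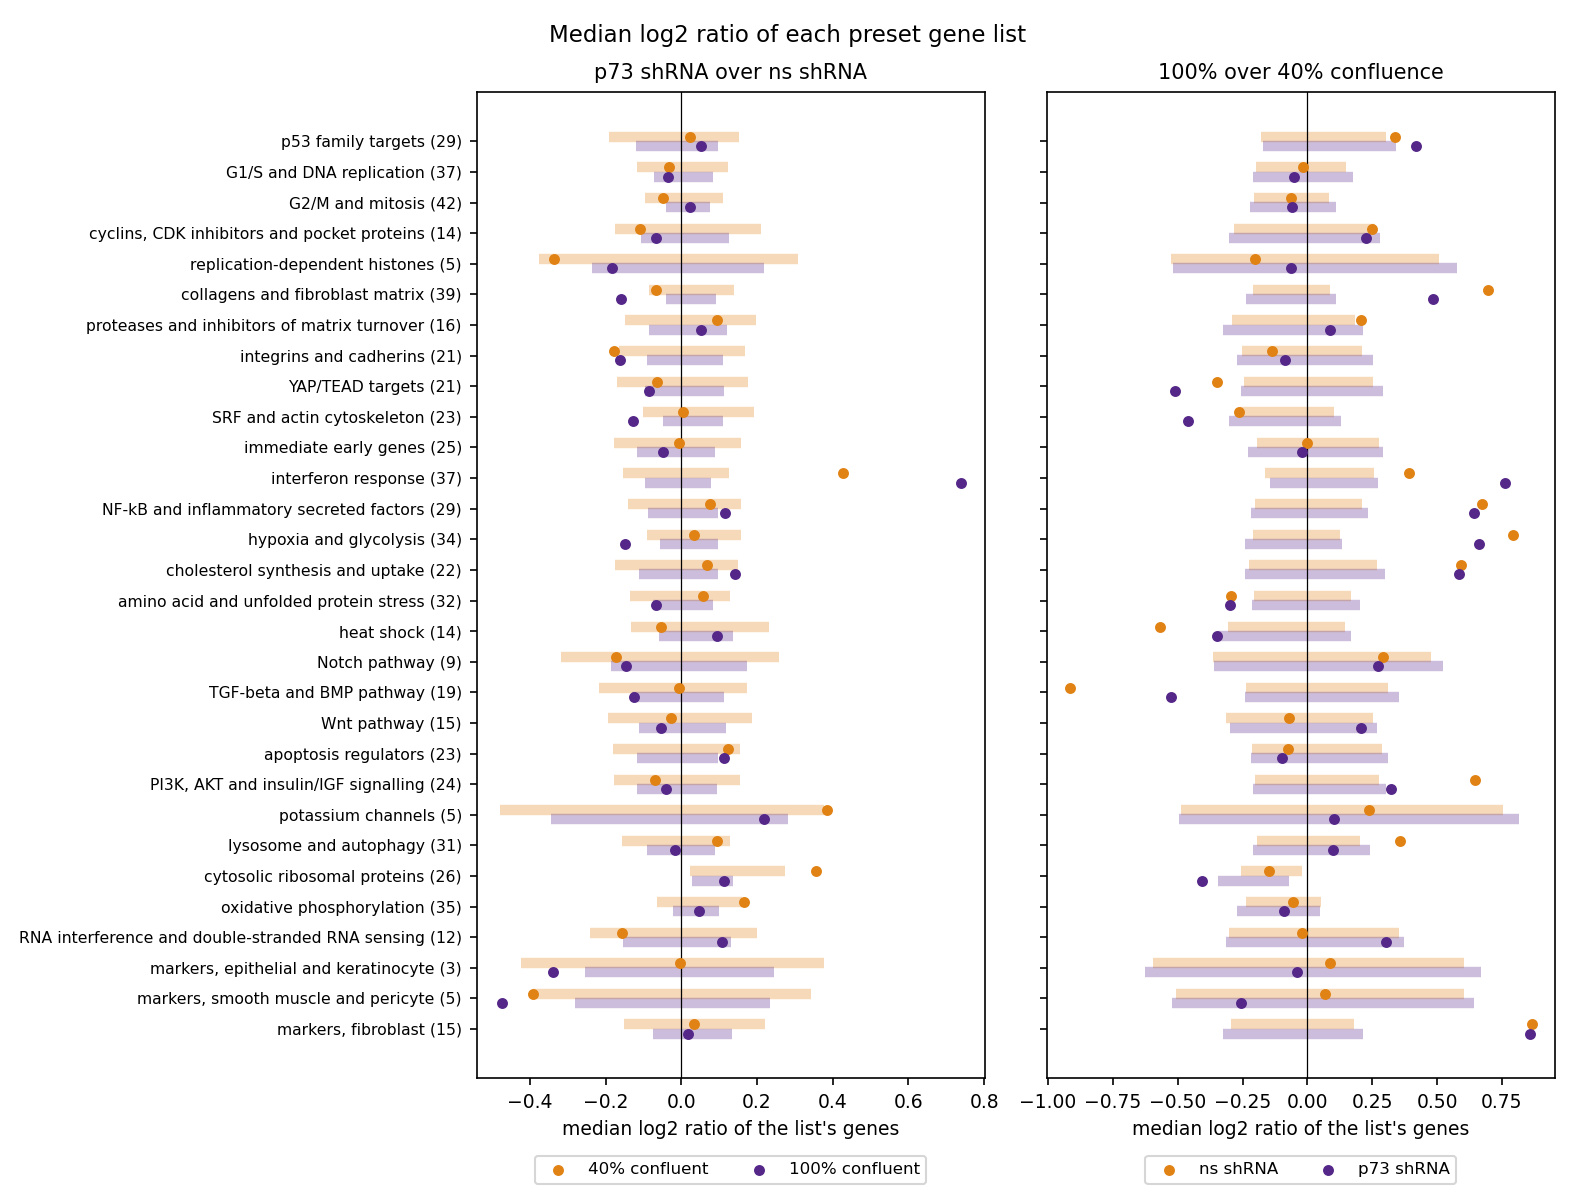
Median log2 ratio of each preset gene list with 3 or more genes above the brightness filter (their number in parentheses), for p73 over ns shRNA at each stage on the left and 100% over 40% confluence with each hairpin on the right, with bars for the central 95% of 10000 random lists matched on mean expression. The interferon list lies furthest right in the left panel (0.43 and 0.74), and fibroblast markers (0.86 for both) and TGF-beta and BMP genes (-0.92 and -0.53) lie at the ends of the right panel.

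The p73 shRNA ratio was set against confluence to ask whether it differs between the stages. The signed log2 ratio was higher by 1 or more at 100% than at 40% for 91 genes and lower by that much for 76. Together these were 2.47% of the genes tested, and the difference has no replicate check and no test. A higher signed ratio can be a smaller change, as for LUM (-1.91 and -0.78). In size, 121 genes were at least 2-fold at 40% and 45 at 100%, again without a replicate check. SPN, a sialoglycoprotein of leukocytes, had the largest positive difference (ratios -0.13 and 2.55), from a fall of the ns shRNA intensity to 21 at 100% against 179 to 205 on the other arrays. HABP4 had ratios of 0.02 and 1.74. The most negative difference was that of the glutathione transferase GSTM2 (1.52 and -0.54). Both comparisons together called 103 genes, where independent lists would share 67.3, and 41 of the 103 moved in the same direction in both; the averages compared are orthogonal but come from the same 4 arrays. Each gene has the same SE in both fits, set by its brightness, so genes with a small SE are more easily called in both. The excess over 67.3 therefore need not reflect a link between the comparisons.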

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

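The differences between stages rest on 1 array per group and were not tested, and no tests here were chosen after the result was seen.

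The 5 genes with the most positive and the 5 with the most negative difference of the p73 shRNA ratio between stages were picked by a rule, and 9 of these 10 had ratios of opposite sign at 40% and 100% confluence. The log2 difference was 2.68 for SPN (ratios -0.13 and 2.55), 1.88 for SBNO1 (-1.25 and 0.63), 1.79 for the RNA sensor IFIH1 (-1.25 and 0.54) and 1.76 for SNX11 (-0.92 and 0.84). It was -2.05 for GSTM2 (1.52 and -0.54), -1.80 for the kinase SIK2 (1.13 and -0.67), -1.68 for WDR62 (0.27 and -1.41), -1.67 for CACNG4 (1.43 and -0.24) and -1.51 for THAP3 (0.57 and -0.94). SPN, with 4 probe sets, rose with p73 shRNA in the additive model (limma adjusted p 0.00542, and 0.156 without the intensity trend) although its ratio at 40% was below 0. Picking the extremes of 6759 genes brings out noise in single arrays.

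The median of the list of RNA interference and double-stranded RNA sensing also changed sign, from -0.16 at 40% to 0.11 at 100%, a difference of 0.26 that was not tested. IFIH1 is on this list and on the interferon list.

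Probe sets with several genes or with none were outside the comparisons. Of 1156 of them above the brightness filter, 42 were at least 2-fold different with confluence for both hairpins, 25 higher and 17 lower, and 0 were so with p73 shRNA at both stages, a count with no test behind it.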

How the results depend on the processing

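The counts without 1 array come from tests chosen after the data were seen; the others were planned. The genes named by size were picked from these same arrays, which favours their call in every setting. The 24 confluence genes named by size kept their call in each setting that measured them. The 24 named by size for p73 shRNA did so with both other pseudocounts and without the intensity trend, and all but TAP2 did after quantile normalization. With the mean of all probe sets only 18 of the 24 remained above the brightness filter. Of these 18, 15 kept their call and CLU, FHL3 and FKBP10 did not, although FHL3 and FKBP10 have 1 probe set each. With quantile normalization 46 genes rose and 59 fell with p73 shRNA, and 104 of these were among the 184. With the pseudocount at the 40th percentile 1 gene was 2-fold higher and 7 were lower at both stages, and 88 differed by stage. Without a filter 1 rose and 3 fell with p73 shRNA and 912 rose and 643 fell with confluence; 67 and 60 were 2-fold with p73 shRNA and 383 and 171 with confluence, the correlations were 0.0739 and 0.417, and 1866 differed by stage. With the filter at the 70th percentile 872 rose with confluence, 1 and 2 were 2-fold with p73 shRNA and 114 and 59 with confluence, and 40 differed by stage, with 4369 genes tested. With the mean of all probe sets 17 rose and 23 fell with p73 shRNA, and 5 were 2-fold lower. Without the intensity trend 26 rose and 48 fell. With the other factor left out, 0 rose and 0 fell with p73 shRNA in limma (58 at an unadjusted p below 0.05, and 0 without the trend, where 72 were), since the confluence effect then enters the error, and 767 rose and 578 fell with confluence. At 1.5-fold the p73 shRNA counts were 32 and 51 and the confluence counts 673 and 384; at 3-fold they were 1 and 4, and 66 and 21, by construction. Without 1 array a single ratio is left, with no test: 21 to 43 genes were 2-fold higher and 24 to 78 lower with p73 shRNA, and 380 to 429 higher and 177 to 178 lower with confluence. Among the lists and the genes named by rule, reversed were the confluence median of the p53 family targets, -0.19 with the filter at the 70th percentile, and the confluence log2 ratio of RPL14, 0.10 with the mean of all probe sets. VIM and RPS16, which that rule does not name for confluence, changed their confluence sign after quantile normalization. Except where stated, the cause was not tested. Of the log2 ratios of genes named by rule over all settings, 873 kept their side of the threshold for p73 shRNA, 121 lost it and 2 gained it; for confluence 904 kept it, 67 lost it and 1 reversed. Of the list medians over all settings, 141 for p73 shRNA and 129 for confluence moved by less than their spread and 38 and 49 by more. No paired analysis of replicates was possible because each group has 1 array; the additive model compares the vectors within each stage. Signal over background limits dim genes such as TP73.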

Other observations

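The complement, MHC class I, metallothionein and ID lists, and the tests on cell density, the hairpin construct, amino acid stress, processing time and the ribosomal list after quantile normalization, were chosen only after the result was seen. Complement components rose at confluence. Of 8 measured above the brightness filter 6 rose and none fell, also adjusted over the list alone, with medians of 1.95 with ns shRNA and 1.38 with p73 shRNA. The proteases C1R (2.00 and 2.27) and C1S (1.90 and 1.57), their inhibitor SERPING1 (2.52 and 1.18) and the central component C3 (2.45 and 1.94) rose. In MHC class I and peptide loading 8 of 13 rose by either adjustment, with medians of 0.81 and 0.57, among them TAPBP (1.35 and 1.04) and the peptidase ERAP1 (0.81 and 1.05). With p73 shRNA TAP2 and the immunoproteasome subunit PSMB9 (0.70 and 0.39) rose in this list, and both calls were lost after quantile normalization, that of PSMB9 also without the intensity trend.

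All 6 members of a list of ID proteins and BMP targets fell at confluence by either adjustment, with medians of -1.65 and -1.71. Of 6 metallothioneins 2 rose with p73 shRNA, MT1H (0.54 and 0.65) and MT1E (0.51 and 0.40), and 5 did so adjusted over the list alone, with medians of 0.52 and 0.25; without the intensity trend 0 rose in limma. EDN1 fell in both comparisons, with ratios of -1.27 and -2.01 for p73 shRNA and -2.14 and -2.87 for confluence. KCNK1 and IGFBP5 fell with p73 shRNA and rose with confluence, where the average for IGFBP5 was 1.12.

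The interferon list was higher with p73 shRNA at both stages. Scaling that depends on brightness is argued against, because the average median was 0.60 (SE 0.09) after a trend on brightness was removed. A difference in cell density between the arrays of both vectors is argued against too: over the 24 named confluence genes the slope of the p73 shRNA ratio on the confluence ratio was -0.0224 (SE 0.0367), where the interferon list's own quotient was 1.01. The SEs in this section are taken across genes, which are not independent replicates. They do not measure the spread between arrays or cultures. A response to the hairpin construct and loss of p73 cannot be told apart, with 0 arrays of a second p73 hairpin or of no hairpin, so the rise may come from either. With TP73 at the floor, loss of p73 itself was not measured.

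The ribosomal protein list had a median of 0.36 with p73 shRNA at 40% confluence. After quantile normalization it was 0.0108, and the 19 other genes as bright as the list had a median of 0.27 (SE across genes 0.0911) before and -0.0647 after it. The list's median brightness lay at the 99.4th percentile of genes, where quantile normalization makes the arrays alike. A real rise of these genes could therefore vanish as well, so the value after it cannot decide the question. A brightness-dependent difference in scaling is a candidate explanation, and so is a rise of the brightest genes whatever they encode. These describe the same feature of that array, and no biological explanation was tested.

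The hypoxia and glycolysis list was higher at confluence. Its average median was 0.71 (SE across genes 0.25) after a trend on brightness was removed, which argues against scaling as the whole cause. The list of amino acid and unfolded protein stress did not rise as a whole, with a median of -0.30 (SE across genes 0.19). Of its 32 members 13 fell and 3 rose, among them DDIT4, which is also on the hypoxia list. That list pools both responses and the test was chosen after the result was seen, so its median excludes neither response. Processing of the stages at different times cannot be told apart from density, with 0 arrays of a stage known to come from another batch. Lower oxygen or other effects of density may underlie the rise, and oxygen was not measured.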
